A study of Mus musculus with 16 samples.

How the data were processed

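RNA was measured by sequencing in 16 libraries of skin from female SKH-1 mice, a hairless strain. The labels place the libraries in 8 groups of 2: epidermis of unexposed and UVB-exposed mice at weeks 2, 15 and 25, and whole skin of unexposed mice and tumors of UVB-exposed mice at week 25. Libraries are named by group and by the number 0 or 1 that the titles give. RNA was extracted with Qiagen AllPrep kits and libraries were made with a standard Illumina protocol, per the labels' protocols. The series also has DNA methylation data, which were not analysed here.

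The deposited values are whole-number counts of reads per gene in 1 table of 24421 genes with mm10 coordinates. Per the submitters' processing notes, reads were handled with HISAT2, Picard, featureCounts and DESeq2 on mm10, with no versions. Per the file headers, the authors counted alignments from which duplicates had been removed. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Reads shared by near-identical genes (the Krtap, Sprr, Lce, Serpinb, Stfa, Gsta and Gbp families) and by overlapping or antisense genes may therefore be split between them, and values of such genes are uncertain. Totals ran from 2905165 to 7959503 counts per library, and no gene held more than 0.224% of a library. The highest value, among genes with at least 500 bases of exon, was 1.83 to 2.11 counts per base in each of the 16 libraries whatever its depth. Removing duplicates sets such a ceiling, so folds of abundant genes can be understated. Where depths differ, abundant genes can also stand too high in the shallower library. Week 2 control 1 over control 0 had a median log2 of -0.29 under 0.02 counts per base, 0.45 at 0.4 to 1 and 0.88 above 1. For whole skin control 1 over control 0 the medians were 0.06, 0.55 and 0.77 in these ranges.

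Counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and groups were compared with edgeR's quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 values are given with the standard error of the fit, in which edgeR adds a prior count of 0.125. CPM values use the TMM sizes of all 16 libraries and are given as mean ± SD over libraries. UVB against control at each week, its difference between weeks and the difference between weeks in controls came from 1 fit of the 12 epidermis libraries (13478 genes, 6 residual degrees of freedom, biological coefficient of variation 19.1%). The effect of UVB as the mean over weeks came from the same libraries with week and treatment as additive terms (8 residual degrees of freedom, 22.7%). Tumor against whole skin was fitted on its 4 libraries (14661 genes, 2 residual degrees of freedom, 29.8%). Tumor against UVB epidermis, and whole skin against control epidermis, came from 1 fit of all 16 libraries (15126 genes, 23.0%).

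These designs, the alternatives, the gene lists and the rule for the genes named were fixed before the data were examined. For each of the main comparisons the rule takes the 8 largest rises and the 8 largest falls (6 and 6 for the mean over weeks). They are drawn from called genes with a mean of at least 5 CPM and no overlap between the arms, leaving out predicted gene models. It also takes up to 4 members with the smallest p of each list and the most abundant member of each marker list, and the genes with the smallest p where no gene is called, for the difference between weeks and for tumor against UVB epidermis. Other genes are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

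The 33 lists cover proliferation, p53 targets, nucleotide excision repair, basal keratinocytes, keratinocyte differentiation, stress keratins and alarm proteins, inflammatory mediators, interferon response, NRF2 and antioxidant genes, DNA methylation machinery, immediate early and AP-1 genes, matrix remodelling, epithelial-mesenchymal transition, hypoxia and glycolysis, EGFR ligands and receptors, WNT, hedgehog and NOTCH, sebaceous and skin lipid genes, hair follicle, circadian clock, RNA quality, and markers of fibroblasts, skeletal muscle, adipocytes, endothelial and mural cells, T and NK cells, dendritic epidermal T cells, Langerhans and dendritic cells, macrophages, neutrophils, mast cells and basophils, B and plasma cells, melanocytes and erythrocytes. Lists with at least 3 tested members were tested with camera (limma 3.58.1), which asks whether members moved more than other genes, at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, was run beside it. List p-values were adjusted over the lists of a comparison. Some lists share genes, such as S100a8 and S100a9 in those of neutrophils and of stress keratins, so their calls are not independent. Some were tested only in part: 6 of 18 neutrophil and 3 of 12 mast cell markers passed the filter in epidermis. Of 18 genes fixed for RNA quality 9 were among the genes counted, so RNA quality was covered in part. Camera made 71 calls over the 3 weeks, their mean and the tumor comparison, and 0 of the 71 held with an estimated correlation, while fry called 32 of them. The count of members passing is given over all genes tested, and also adjusted over the list alone.

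A gene with 0 counts in an arm is given a lower bound of its fold, against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with a 95% exact binomial interval. These floors and intervals cover counting error only.

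The steps were tested on simulated data drawn from the real means and library sizes, with 200 genes changed. Each gene had the same mean in all libraries before the change and a single dispersion, and genes were drawn independently. No ceiling per base, length trend or deviating library was built in. The rates hold for such data and may differ in the real libraries, above all in whole skin, whose replicates stood far apart. EdgeR recovered 81% of 4-fold and 31.2% of 2-fold changes at week 2 with 4 false calls (13201 genes). At week 15 it recovered 79.8% and 44.2% with 6 false calls, at week 25 80.0% and 29.5% with 4 (13184 genes each), and for the mean over weeks 98.0% and 74.2% with 7 (13191 genes). For tumor against whole skin it recovered 60.0% and 5.05% with 11 false calls (14473 genes), for tumor against UVB epidermis 73.7% and 22.4% with 4 (14632 genes), and for whole skin against control epidermis 75.8% and 21.4% with 6 (14641 genes). The test of a difference between weeks recovered 68.7% and 12% with 7 false calls (13189 genes), and that between control weeks 77.3% and 25% with 10 (13194 genes).

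Alternatives were median-of-ratios size factors, no filter, a stricter filter (5 CPM in 2 libraries), DESeq2 1.42.0, a block for the title's number, other sets of libraries in the fit and leaving out each library in turn. Alternatives added after seeing the data were counts corrected for the ceiling per base (genes above 0.9 of it left out), genes under 0.4 counts per base only, each library's trend over exon length taken out as an offset, and tumor against whole skin without whole skin control 1.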

Results

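The series follows the skin transcriptome of SKH-1 mice, a hairless strain used in photocarcinogenesis work, through chronic exposure to ultraviolet B (UVB). Exposed mice received 60 mJ/cm2 in 2 sessions per week, and control mice were not exposed. Epidermis was collected from both arms at weeks 2, 15 and 25, and whole skin of control mice and tumors of exposed mice were collected at week 25, with 2 libraries in each of the 8 groups. Deposited gene counts summed to 2905165 in the shallowest library (week 2 control 1) and to 7959503 in the deepest (whole skin control 0). The others held 4854612 to 7175363. Replicates of every group differed by more than sampling noise, with a chi-square of 4.62 (tumor) to 46.2 (whole skin control) per degree of freedom. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Log2 values are UVB over control, ± standard error, and levels are mean CPM ± SD over 2 libraries unless another n is given.

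The effect of UVB as the mean over weeks was asked of 6 UVB and 6 control epidermis libraries. A gene called here need not have changed at each week. Tested week by week, 122 genes were called up and 117 down at every week. The cytokine gene Il19 (mm10 chromosome 1, 130932656 to 130939241) stood at 18.8 ± 11.3 CPM in UVB and 0.145 ± 0.172 in control epidermis (n = 6 each), a rise of 6.66 ± 0.68 on the log2 scale (adjusted p = 9.15e-05). Cdhr1, a cadherin gene best known from photoreceptors (chromosome 14, 37077849 to 37098311), rose by 4.88 ± 0.28 (adjusted p = 3.41e-06), from 1.48 ± 0.526 to 43.8 ± 11.6 CPM. Svep1, which encodes an extracellular adhesion protein, rose by 5.59 ± 0.56 (adjusted p = 8.89e-05), and the monocyte chemokine gene Ccl7 by 5.41 ± 0.63 (adjusted p = 0.00023). Ddit4l and Lgi2 rose by 4.51 ± 0.56 and 4.44 ± 0.56. Genes of the hair shaft fell. The hair keratin gene Krt39 (chromosome 11, 99514624 to 99521258) changed by -4.78 ± 0.52 (adjusted p = 0.000148), the hair desmoglein gene Dsg4 by -4.62 ± 0.63, the keratin-associated gene Krtap5-4 by -4.63 ± 0.80. Mrgprb2, which encodes a mast cell receptor, changed by -4.47 ± 0.53 (adjusted p = 0.000243), with 1.78 ± 0.979 against 41.3 ± 32.7 CPM (n = 6 each). Capn8 and Lyg2 also fell, by 4.51 and 4.47 on that scale. In all, 3973 of 13478 genes were called, 1938 up and 2035 down, of which 924 and 639 changed at least 2-fold. The 12 genes named here were called under each of the 20 alternatives run for this comparison, with adjusted p-values up to 0.00514.

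Among the gene lists, cell division genes rose as the mean over weeks. Lists called for the mean need not have moved at each week, and the weeks are given below. Of 30 proliferation genes 28 were called up and none down (28 and 0 adjusted over the list alone, camera adjusted p = 5.17e-22, adjusted p = 0.36 with an estimated correlation). The ribonucleotide reductase gene Rrm2 rose by 1.37 ± 0.11. Of 30 interferon response genes 23 rose and none fell (camera adjusted p = 3.35e-11, adjusted p = 0.551 with an estimated correlation), among them the T cell chemokine genes Cxcl10 (3.71 ± 0.42) and Cxcl9 (3.75 ± 0.49). Stress keratins and alarm proteins had 21 of 35 up and 2 down (camera adjusted p = 2.3e-06, adjusted p = 0.551 with an estimated correlation). Inflammatory mediators had 11 of 19 up and 3 down (2.76e-05, adjusted p = 0.36 with an estimated correlation), including the alarmin gene Il33 (2.03 ± 0.23) and the prostaglandin synthase gene Ptgs2 (2.60 ± 0.37). Hair follicle genes had 23 of 29 down and none up (camera adjusted p = 2.95e-17, adjusted p = 0.36 with an estimated correlation). Macrophage markers (8 of 13 up, 0.000896), neutrophil markers (4 of 6 up, 0.0012) and clock genes (9 of 18 down, 1 up, 0.0247) passed camera, with adjusted p = 0.551, 0.36 and 0.403 with an estimated correlation. Differentiation genes (6 of 29 down, 1 up, 0.0215), matrix remodelling genes (5 of 20 up, 0.0292) and Langerhans and dendritic cell markers (4 of 14 up, 0.018) also passed, with adjusted p = 0.685 with an estimated correlation for each. Dnmt3l, which encodes a cofactor of the de novo DNA methyltransferases (chromosome 10, 78042287 to 78063622), rose by 3.60 ± 0.30 (adjusted p = 3.12e-05), while Dnmt3a fell by 0.85 ± 0.15 (adjusted p = 0.00154).

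**Figure D1:**
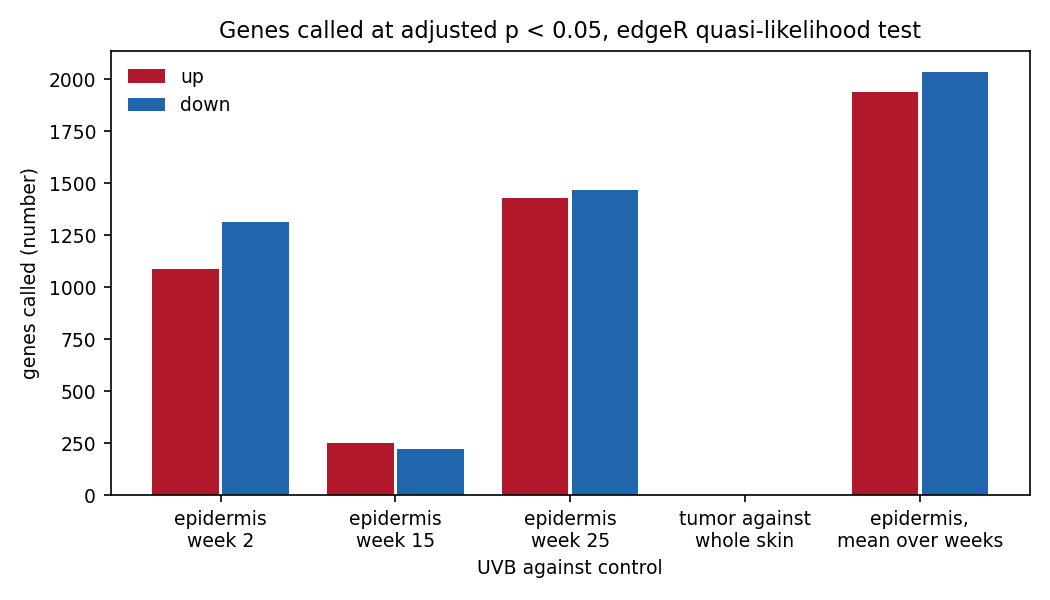
Bars give the number of genes called up (red) and down (blue) in UVB against control for epidermis at each week, for tumor against whole skin and for the mean over the 3 weeks, with 2 libraries per group. Calls numbered 1090 up and 1313 down at week 2, 250 and 221 at week 15, 1430 and 1468 at week 25, 0 in tumor, and 1938 and 2035 for the mean.

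At week 2 the question was the early response. Eda2r, a p53 target that encodes a receptor for ectodysplasin (chromosome X, 97333841 to 97377209), stood at 87.2 ± 6.95 CPM in UVB and 4.16 ± 1.86 in control epidermis, a rise of 4.46 ± 0.37 (adjusted p = 0.00129). The protease inhibitor genes Serpinb1a and Spink7 rose by 4.25 ± 0.48 and 4.20 ± 0.54, the receptor phosphatase gene Ptprz1 by 4.25 ± 0.53 and Cdhr1 by 4.20 ± 0.45 (adjusted p from 0.00249 to 0.00307). Cxcl9 rose by 4.66 ± 1.16 (adjusted p = 0.0218). Il19 and Gpr179, with 2 counts each over the control libraries, were 63.9 (95% counting interval 17.4 to 532) and 39.0 (10.6 to 326) times higher (adjusted p = 0.0103 and 0.00954). Hair shaft genes were the largest falls: Krtap19-5, Krtap5-4 and Krtap19-2, which encode keratin-associated proteins, had no counts in UVB epidermis and were at least 213-, 186- and 155-fold lower (adjusted p = 0.0168, 0.00478 and 0.012). Krtap19-3 fell by 7.26 ± 1.65. Crisp1 (ratio 236, interval 64.8 to 1957), the transporter gene Slco5a1 (ratio 190, interval 33.4 to 7547), Krtap19-4 (ratio 305, interval 54.2 to 12121) and Krtap27-1 (ratio 188, interval 33.2 to 7490) were lower in UVB epidermis too. In all, 2403 of 13478 genes were called, 1090 up and 1313 down (617 and 928 at least 2-fold), and of all tested genes 60.0% had both UVB libraries on one side of both controls, where chance gives 33.3% on average. Genes are not independent, so such a share can lie far from 33.3% without an effect, here and at the other weeks. Only the 4 libraries compared gave 684 calls.

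Proliferation genes rose almost without exception at week 2, with 28 of 30 up and none down (28 and 0 adjusted over the list alone, camera adjusted p = 7.36e-23, adjusted p = 0.326 with an estimated correlation). The cell cycle marker gene Mki67 went from 23.0 ± 0.168 to 101 ± 21.3 CPM (2.09 ± 0.29, adjusted p = 0.00417), and Top2a and Ccnb1 rose by 2.68 ± 0.40 and 3.42 ± 0.56. Of 30 p53 targets 10 rose and none fell (10 and 1 adjusted over the list alone, 0.00107, adjusted p = 0.326 with an estimated correlation). The cyclin gene Ccng1 rose by 2.30 ± 0.22 (adjusted p = 0.00129), and the BH3-only gene Pmaip1 and the apoptosome gene Apaf1 by 2.26 ± 0.33 and 2.45 ± 0.52. Hypoxia and glycolysis genes had 7 of 25 up (8 adjusted over the list alone, 0.00213, adjusted p = 0.326 with an estimated correlation), led by Hk2 (1.44 ± 0.28) and Slc2a1 (1.30). Hair follicle genes had 23 of 29 down and none up (26 down adjusted over the list alone, 1.07e-14, adjusted p = 0.326 with an estimated correlation), with the keratin genes Krt75 at -4.61 ± 0.55 and Krt86 at -5.44 ± 0.88. Fewer members moved in the DNA methylation list, where Dnmt3l rose by 2.60 ± 0.41, the replication-coupled genes Hells and Uhrf1 by 2.31 and 1.68, and Zbtb38 by 1.36. It had 4 of 20 up (6 up and 1 down adjusted over the list alone, 0.0212, adjusted p = 0.657 with an estimated correlation). Basal keratinocyte genes had 3 of 13 up (4 and 1 down adjusted over the list alone, 0.0264, adjusted p = 0.67 with an estimated correlation): Itga6, Trp63 and Krt5. Stress keratins had 6 of 35 up and 2 down (7 and 2 adjusted over the list alone, 0.0234, adjusted p = 0.67 with an estimated correlation), the falls being the antimicrobial genes S100a7a (-4.33 ± 0.64) and Defb4 (-3.68 ± 0.76). Inflammatory mediators had 4 of 19 up and 1 down (6 and 2 adjusted over the list alone, 0.042, adjusted p = 0.596 with an estimated correlation), with Il33 at 1.91 ± 0.37 and the chemokine gene Ccl20 at -1.33. Differentiation genes had 2 of 29 up (Rptn, Tgm3) and 3 down (2 and 9 adjusted over the list alone, camera down, 0.0159, adjusted p = 0.74 with an estimated correlation). Their sum was 14900 and 24564 CPM in controls 0 and 1 and 16210 and 14387 in UVB, so the fall rests on control 1. Without it the median went from -0.62 to -0.09, and none was called without it, UVB 0 or UVB 1, against 2 up and 19 down without control 0. Control 1 was also higher in RNA quality genes (4799 against 2718 CPM). Abundant genes at large stood higher in it than in control 0, by a median log2 of 0.45 at 0.4 to 1 counts per base and 0.88 above 1. Its list sums at week 2 may therefore in part reflect its lower depth.

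Markers of other cell types moved at week 2 as well. Fibroblast markers had 4 of 15 down and 1 up (8 and 1 adjusted over the list alone, camera down, 0.00944, adjusted p = 0.596 with an estimated correlation), with Dcn at -2.33 and Fbln1 at 1.25. Adipocyte markers had 3 of 8 down (0.0127, adjusted p = 0.326 with an estimated correlation), led by Fabp4 (-4.39 ± 0.66). Melanocyte markers had 2 of 6 down (0.026, adjusted p = 0.339 with an estimated correlation), including Mitf at -2.18 ± 0.36. Mast cell markers had 2 of 3 down (0.0494, adjusted p = 0.326 with an estimated correlation), and dendritic epidermal T cell markers 2 of 7 down (0.0414, adjusted p = 0.67 with an estimated correlation), Cd3g at -1.80 ± 0.41 and Cd7 at -1.43. Sebaceous genes had 1 of 23 down, Mogat1 (camera 0.026, adjusted p = 0.67 with an estimated correlation). They summed to 3698 and 6964 CPM in controls 0 and 1 and to 4090 and 3617 in UVB, and without control 1 their median went from -0.57 to 0.08. Without control 0 it was -0.88 with 9 down, and none was down without UVB 1. The mast cell median went from -3.23 to 0.17 without control 0. Mrgprb2 alone held 56.5 and 87.6 CPM of mast cell sums of 61.2 and 91.4 CPM in controls 0 and 1. In whole skin controls 0 and 1 it stood at 35.4 and 6.96 CPM, while the sums were 177 and 382 CPM. Its fall, here or at other weeks, does not by itself show fewer mast cells. Neutrophil markers had 3 of 6 up and 1 down (5 and 1 adjusted over the list alone, 0.0101, adjusted p = 0.326 with an estimated correlation), Stfa2 at 1.12, S100a8 at 0.64, the receptor gene Trem1 at least 21.6-fold higher, and Mmp9 at -2.31. Camera did not call interferon response genes (2 of 30 up: Cxcl9 and Cxcl10, 0.438), nucleotide excision repair (4 of 24 up, with Ercc1 at 1.25, 0.123), NRF2 genes (4 of 26 up, with Slc7a11 at 2.65 ± 0.34, and 3 down, 0.429, median -0.00, mean 0.06), or AP-1 genes (0 of 20, 0.755, camera down, median -0.04, mean 0.05). It did not call matrix remodelling (1 of 20 up, 4 down, 0.483), epithelial-mesenchymal transition (3 of 14 up, 3 down, 0.754), EGFR ligands and receptors (2 of 12 up, 0.483), WNT, hedgehog and NOTCH genes (2 of 24 up, 4 down, 0.601) or the clock (3 of 18 up, 5 down, 0.324). Nor did it call markers of muscle (1 of 18 down, 0.438), endothelium (3 of 9 down, 0.15), T and NK cells (2 of 15 down, 0.149), or Langerhans cells (1 of 14 up, 0.483). The same held for macrophages (1 of 13 up, 1 down, 0.745, median -0.53, mean 0.05), B cells (0 of 3, 0.988, camera down, median 0.15, mean -0.21) and RNA quality genes (0 of 9, 0.361). Erythrocyte markers had 2 tested members, too few for a test, and Alas2 stood at 0.567 to 9.27 CPM over the epidermis libraries. Leaving out UVB 1 left 125 calls at week 2, against 995 without UVB 0, 1106 without control 1 and 4377 without control 0. It left 3 proliferation genes, 3 p53 targets, 1 hair follicle gene and no hypoxia, fibroblast or mast cell gene called, p53 targets also numbered 3 without control 1, and no fibroblast or mast cell gene was called without UVB 0.

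At week 15 a chitinase-like gene and 3 interferon-induced genes were among the 8 largest rises. Chil4, a chitinase-like gene of type 2 inflammation (chromosome 3, 106201491 to 106219479), stood at 165 ± 29.2 CPM in UVB and 0.359 ± 0.0579 in control epidermis (8.75 ± 1.33, adjusted p = 0.011). The interferon-induced genes Zbp1 and Ifi27l2a rose by 5.45 ± 1.01 (adjusted p = 0.0242) and 5.17 ± 0.73 (adjusted p = 0.00807), and Ifi44 was 48.7 times higher (counting interval 16.4 to 239). Svep1 rose by 5.54 ± 0.71 (adjusted p = 0.00511), Ddit4l was 152 times higher (interval 27.0 to 6054), Il19 66.4 times (18.1 to 554), and the potassium channel gene Kcnt1, with no counts in the controls, at least 44.3-fold (adjusted p = 0.015). Hair shaft genes were again lower, with Krt39 at -4.25 ± 0.80, Krt31 at -4.06 ± 0.90 and Dsg4 at -4.33 ± 1.05, and so was Mrgprb2 at -4.50 ± 1.07 (adjusted p from 0.0244 to 0.0493). Also lower were Smim18 (-5.19 ± 1.06), Csdc2 (-4.42), Slc38a3 (-4.22) and Rab11fip4 (-4.09). In all, 471 of 13478 genes were called, 250 up and 221 down (231 and 187 at least 2-fold), and 52.0% of tested genes had arms that did not overlap (chance 33.3%). DESeq2 called 1006 genes, no filter gave 1146 and all 16 libraries in 1 fit 234.

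Of 30 interferon response genes 15 rose at week 15 and none fell (26 and 0 adjusted over the list alone, camera adjusted p = 2.98e-22, adjusted p = 0.243 with an estimated correlation). The antiviral synthetase genes Oas2 and Oas3 rose by 3.72 ± 0.60 and 2.79 ± 0.44. Inflammatory mediators had 6 of 19 up and 1 down (10 and 1 adjusted over the list alone, 2.33e-05, adjusted p = 0.243 with an estimated correlation), with Ccl7 at 4.85 ± 0.57, Ccl2 at 3.87 and Il1b at 1.70 ± 0.32. Proliferation genes had 4 of 30 up over all genes and 25 adjusted over the list alone (2.37e-17, adjusted p = 0.361 with an estimated correlation), with Rrm2 at 1.34 ± 0.18. Of 30 p53 targets 6 rose (8 and 1 down adjusted over the list alone, 0.000385, adjusted p = 0.243 with an estimated correlation), Ccng1 at 1.36 ± 0.20 and Eda2r at 1.98 ± 0.32. Stress keratins had 3 of 35 up and 1 down (12 and 2 adjusted over the list alone, 0.000653, adjusted p = 0.673 with an estimated correlation), with Lce3e at 2.88 and S100a7a at -3.30 ± 0.63. Macrophage markers had 1 of 13 up, the scavenger receptor gene Cd163 at 4.47 ± 0.71 (5 adjusted over the list alone, 0.000653, adjusted p = 0.243 with an estimated correlation). Neutrophil markers had 2 of 6 up (Stfa2 at 1.80 ± 0.17, Trem1 at least 7.38-fold, camera 0.00291, adjusted p = 0.243 with an estimated correlation). Langerhans and dendritic cell markers had 0 of 14 up (3 adjusted over the list alone, 0.000114, adjusted p = 0.384 with an estimated correlation). Hair follicle genes had 10 of 29 down (24 adjusted over the list alone, 1.33e-13, adjusted p = 0.384 with an estimated correlation). Dendritic epidermal T cell markers had 2 of 7 down (3 adjusted over the list alone, 0.000653, adjusted p = 0.547 with an estimated correlation), Cd7 at -2.62 ± 0.44 and Cd3g at -1.86 ± 0.39. The other lists were not called (camera adjusted p from 0.0707 to 0.896), though Dnmt3l rose by 3.85 ± 0.39 (adjusted p = 0.00186). Without control 0 or UVB 1 the week 15 calls numbered 31 and 26, and no interferon, proliferation or hair follicle gene was among them. Without UVB 0 they were 140 (interferon 7, proliferation 1, hair follicle 0) and without control 1 they were 1463 (interferon 12, proliferation 26, hair follicle 15).

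**Figure D2:**
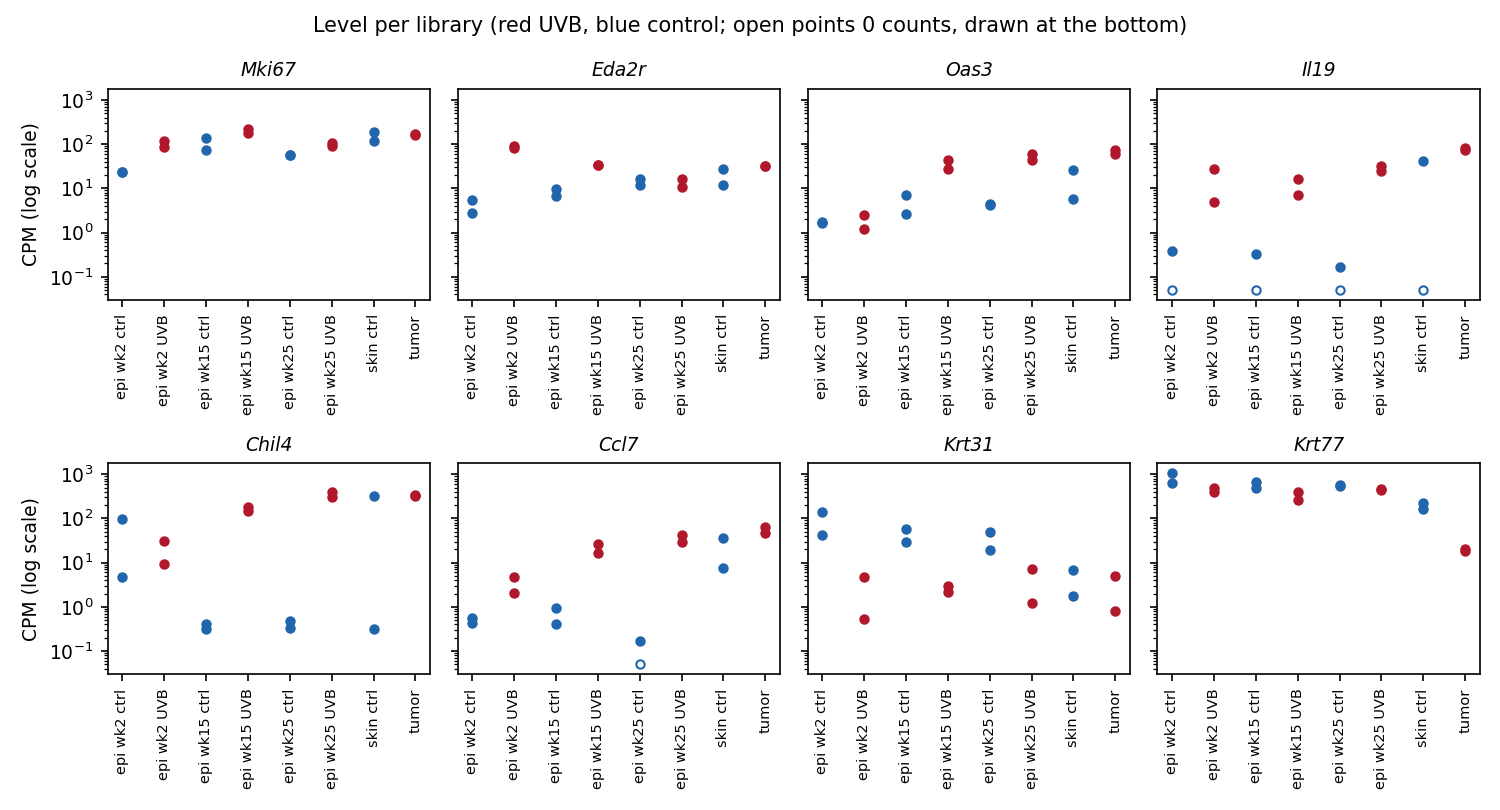
Points give the level of 8 genes in each of the 16 libraries in CPM on a log axis, by group, with UVB in red and control in blue. Chil4 stood at 0.31 to 0.47 CPM in the week 15 and 25 control epidermis and in whole skin control 0, and at 144 to 389 CPM in UVB epidermis of the same weeks, while whole skin control 1 stood at 315 CPM and the week 2 controls at 98.52 and 4.63 CPM.

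By week 25 the largest rises were of chemokine, matrix and type 2 inflammation genes. Chil4 reached 344 ± 63.5 CPM against 0.407 ± 0.0878 (9.64 ± 1.28, adjusted p = 0.00213). The eosinophil chemokine gene Ccl11 had no counts in the controls and was at least 71.3-fold higher, and its neighbour Ccl7 was 427 times higher (counting interval 76.2 to 16904). Svep1 was 481 times (85.9 to 19037), Il19 345 times (61.5 to 13665) and the beta-glucan receptor gene Clec7a 123 times higher (21.7 to 4897, adjusted p of these genes from 0.000469 to 0.00304). The collagenase gene Mmp13 (chromosome 9, 7272514 to 7283333) rose by 6.45 ± 0.76 (adjusted p = 0.00149), from 0.563 ± 0.309 to 51.8 ± 28.4 CPM. The falls were of hair genes, with Dsg4 at -4.26 ± 1.19, Krt72 at -3.64 ± 0.93, Krt26 at -3.53 ± 0.97, Krt83 at -3.48 ± 1.13 and Krtap26-1 at -3.98 ± 1.01. Mrgprb2 (-3.97 ± 0.91), Rab11fip4 and the ligand gene Tnfsf18 fell too (all 8 at adjusted p from 0.014 to 0.0487). In all, 2898 of 13478 genes were called, 1430 up and 1468 down (1141 and 546 at least 2-fold), with 70.8% of tested genes not overlapping between arms (chance 33.3%). Only the 4 libraries compared gave 4562 calls and all 16 in 1 fit 1779. The 7 rises named here were called under all 14 alternatives of this comparison.

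At week 25 immune, barrier and stromal lists rose together. Of 30 interferon response genes 23 rose and none fell (26 and 0 adjusted over the list alone, camera adjusted p = 1.05e-14, adjusted p = 0.233 with an estimated correlation), Mx2 at 4.54 ± 0.62 and Oas3 at 3.55 ± 0.44. Stress keratins had 23 of 35 up and none down (24 and 0 adjusted over the list alone, 9.1e-10, adjusted p = 0.233 with an estimated correlation), including the gap junction genes Gjb6 (2.20 ± 0.26) and Gjb2 (1.53 ± 0.20). Inflammatory mediators had 9 of 19 up and 1 down (10 and 2 adjusted over the list alone, 1.91e-08, adjusted p = 0.0924 with an estimated correlation), Il1b at 3.39 ± 0.33 and Il33 at 2.59 ± 0.36. Macrophage markers had 10 of 13 up (7.73e-09, adjusted p = 0.0924 with an estimated correlation), the receptor gene Csf1r at 2.46 ± 0.27 and the complement gene C1qc 40.0 times higher (interval 10.7 to 336). Langerhans and dendritic cell markers had 10 of 14 up (11 adjusted over the list alone, 4.66e-09, adjusted p = 0.163 with an estimated correlation), Cd86 at 2.86 ± 0.35. Neutrophil markers had 5 of 6 up (2.09e-06, adjusted p = 0.0924 with an estimated correlation), Stfa2 at 2.88 ± 0.18 (adjusted p = 6.1e-05). The most abundant of them, S100a9, is also in the stress keratin list and stood at 47.7 to 79.5 CPM in the control epidermis libraries. These calls, here or at other weeks, do not by themselves show more neutrophils. Matrix remodelling genes had 11 of 20 up (15 adjusted over the list alone, 7.73e-09, adjusted p = 0.163 with an estimated correlation), Tnc at 3.63 ± 0.50. Epithelial-mesenchymal transition genes had 6 of 14 up (7 adjusted over the list alone, 0.00212, adjusted p = 0.233 with an estimated correlation), the integrin gene Itga5 at 3.36 ± 0.46. Fibroblast markers had 11 of 15 up (11 adjusted over the list alone, 2.95e-06, adjusted p = 0.266 with an estimated correlation), the collagen genes Col1a2 and Col3a1 at 4.30 ± 0.77 and 4.81 ± 0.88. Col3a1 stood at 54.9 and 11.2 CPM in the UVB libraries and at 2.07 and 0.313 in the controls. Proliferation genes had 14 of 30 up (23 adjusted over the list alone, 1.78e-08, adjusted p = 0.484 with an estimated correlation). Without control 0, control 1, UVB 0 and UVB 1 in turn, the week 25 calls numbered 936, 704, 519 and 976, interferon genes 24, 8, 12 and 11, stress keratins 6, 18, 10 and 9, and matrix genes 7, 5, 6 and 10. In the same order, macrophage markers numbered 6, 3, 3 and 8, Langerhans markers 9, 3, 5 and 9, fibroblast markers 4, 1, 1 and 9, and proliferation genes 1, 2, 1 and 5.

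Fewer lists fell at week 25. Hair follicle genes had 15 of 29 down (20 down and 1 up adjusted over the list alone, camera adjusted p = 3.53e-06, adjusted p = 0.519 with an estimated correlation). Clock genes had 8 of 18 down and none up (9 and 0 adjusted over the list alone, 0.00271, adjusted p = 0.163 with an estimated correlation), Cry1 at -1.14 ± 0.17 and Arntl at -1.11 ± 0.21. They summed to 2380 and 2279 CPM in the week 25 controls and to 1615 and 1712 in UVB. At weeks 2 and 15 the controls held 1594 to 1888 CPM and the UVB libraries 1509 to 1574. The size of the fall at week 25 thus went with high sums in the controls of that week. EGFR ligands and receptors had 5 of 12 down and 1 up (7 and 1 adjusted over the list alone, 0.0219, adjusted p = 0.317 with an estimated correlation), Egfr at -0.94 ± 0.16. RNA quality genes had 3 of 9 down, all heat shock genes (camera 0.03, adjusted p = 0.331 with an estimated correlation), Hsph1 at -1.62 ± 0.23. Camera did not call p53 targets (3 of 30 up, 4 down, 0.771, camera down, median -0.03, mean 0.08), nucleotide excision repair (1 of 24 up, 2 down, 0.771, camera down, median -0.07, mean 0.01), or NRF2 genes (4 of 26 up, 3 down, 0.972). It did not call hypoxia genes (3 of 25 up, 1 down, 0.397), T and NK cell markers (3 of 15 up, 0.174) or DNA methylation genes (1 of 20 up and 4 down, 0.972, camera down while the median of 0.09 and the mean of 0.26 were above 0). Among the latter Dnmt3l rose by 4.29 ± 0.42 (adjusted p = 0.00072) and Dnmt3a fell by 1.23 ± 0.22 (adjusted p = 0.00614). Dnmt3a was also higher in week 25 controls than in week 2 controls. The remaining lists were not called (0.159 to 0.972). Across genes, the week 25 log2 fold was negatively related to exon length (Spearman correlation -0.318 over 13478 genes, which are not independent). With each library's length trend taken out, 1982 genes were called, 60.4% of them up against 49.3% before, with 4 clock genes, 3 EGFR genes and no DNA methylation gene called down. Without control 0, control 1, UVB 0 and UVB 1 in turn, hair follicle falls numbered 0, 2, 1 and 0, clock falls 2, 3, 1 and 2, and EGFR falls 2, 1, 0 and 2.

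**Figure D3:**
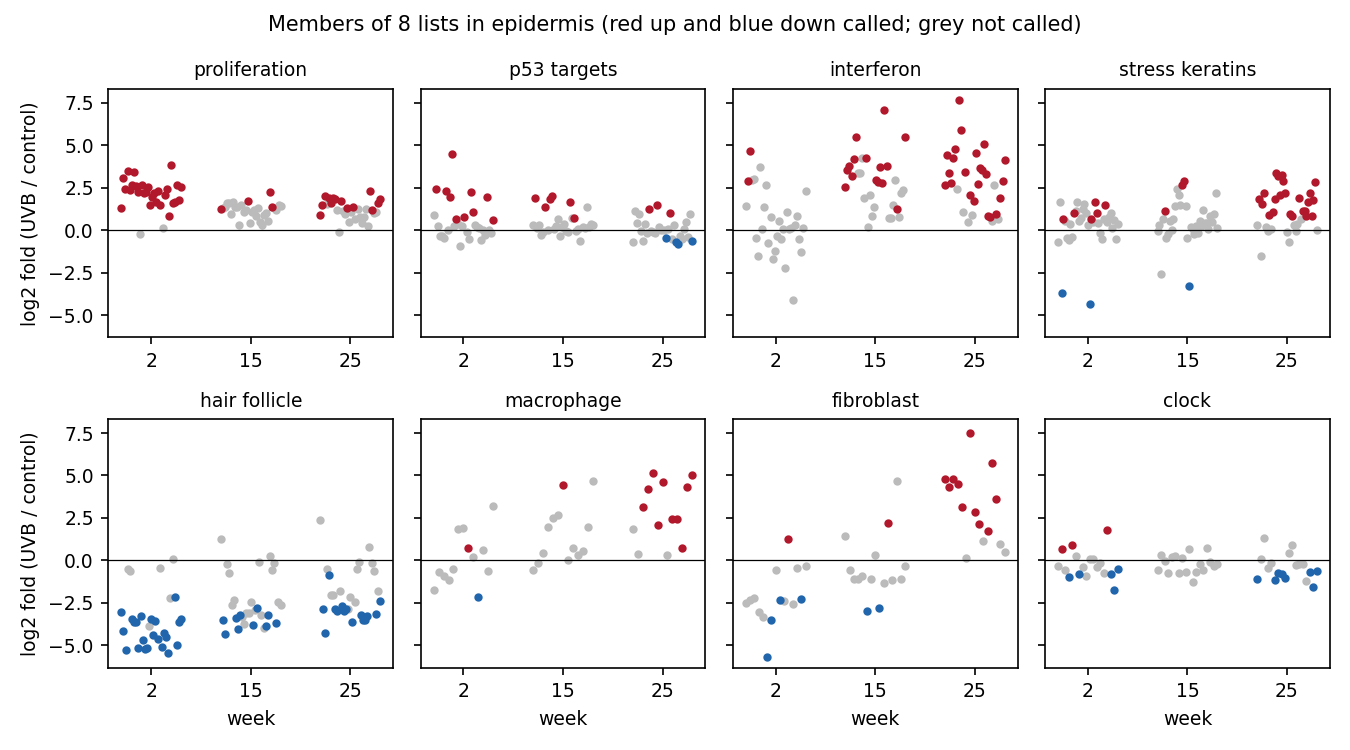
Points give the log2 fold of UVB over control for each tested member of 8 lists at weeks 2, 15 and 25 in epidermis, red and blue where called up and down and grey where not called (2 libraries per group). Proliferation genes called up numbered 28, 4 and 14 over the weeks, interferon genes 2, 15 and 23, and hair follicle genes called down 23, 10 and 15.

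The weeks were compared by the overlap of their calls, and no libraries were shared between them. Weeks 2 and 15 shared 145 rises (20.2 if independent) and 181 falls (21.5), with 0 genes called in opposite directions. Weeks 15 and 25 shared 214 rises (26.5) and 142 falls (24.1) with 1 opposite, and weeks 2 and 25 shared 326 rises (116) and 313 falls (143) with 131 opposite. Across genes, which are not independent replicates, Pearson correlations of log2 folds were 0.68, 0.69 and 0.39. At all 3 weeks 240 genes were called, 122 up, 117 down and 1 with mixed sign. Among them were the transcription factor gene Tcf23 (mean over weeks 3.65 ± 0.20, adjusted p = 3.38e-06), the hyaluronan synthase gene Has3 (3.12 ± 0.30) and the adhesion gene Mcam (3.79 ± 0.33), chosen after their values were seen.

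Whether the UVB effect differed between weeks was tested directly. Over the 3 weeks together 215 genes differed, and between weeks 25 and 2 there were 1067, of which 449 had a higher and 618 a lower UVB effect at week 25. For weeks 15 against 2 and 25 against 15, edgeR called 0 genes, with 1190 and 1315 at an unadjusted p under 0.05, 50 and 63 called by DESeq2 and 26 and 15 with no filter. Leaving out 1 library gave 800 (week 2 control 0) and 2 (week 2 control 1) for the former, and 1 each (week 15 control 0, week 25 UVB 1) for the latter. Eda2r went from 4.46 at week 2 through 1.98 at week 15 to -0.04 at week 25 (adjusted p = 0.0171), with UVB levels of 87.2, 33.8 and 13.7 CPM and control levels of 4.16, 8.32 and 14.1 CPM. The RNA silencing gene Ago2 (chromosome 15, 73101625 to 73184947) went from 1.59 through 0.21 to -1.67 (adjusted p = 0.00459), and its control level went from 18.6 through 45.2 to 114 CPM while its UVB level went from 57.9 through 53.2 to 35.9 CPM. The cathepsin gene Ctsz went the other way, from -3.03 through -0.84 to 0.90 (adjusted p = 0.0171). Between weeks 25 and 2, p53 targets had 5 of 30 with a lower effect and none with a higher one (7 and 0 adjusted over the list alone, camera adjusted p = 0.000921, adjusted p = 0.25 with an estimated correlation), Ccng1 by -1.97. Mean log2 CPM of p53 targets rose in controls between these weeks, from 5.666 and 5.510 to 5.929 and 5.947. Matrix genes had 8 of 20 with a higher effect (5.03e-08, adjusted p = 0.235 with an estimated correlation), among them Mmp14 by 2.41, and fibroblast markers 9 of 15 (2.1e-10, adjusted p = 0.235 with an estimated correlation). Without single libraries the 1067 became 71 (week 2 UVB 1), 85 (week 25 control 1), 102 (week 25 UVB 0), 189 (week 2 UVB 0), 278 (week 25 UVB 1), 537 (week 25 control 0), 643 (week 2 control 1) and 3454 (week 2 control 0). With the length trend removed it was 666 (55.6% higher, against 42.1%), and the 215 became 92. DESeq2 gave 1758 and 1123, and no filter 1612 and 794. Without single libraries the 215 became 2280 (week 2 control 0), 2 and 1 (week 2 UVB 0 and 1), 578 and 393 (week 15 controls 0 and 1), 15 each (week 15 UVB 0 and 1), 4 and 1 (week 25 controls 0 and 1) and 2 and 10 (week 25 UVB 0 and 1).

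Control epidermis itself differed between collection times. Between weeks 25 and 2, 1848 genes differed, 1142 higher and 706 lower at week 25, and 3 genes differed between weeks 15 and 2. DESeq2 gave 3030 and 1297 and no filter 2808 and 1075, and the 3 became 1 by median-of-ratios size factors, on saturation-corrected counts or with the length trend removed and 0 with a stricter filter. Without single libraries the 1848 became 4588 and 350 (week 2 controls 0 and 1) and 250 and 155 (week 25 controls 0 and 1). The share that was higher went from 61.8% to 54.7%, 72.3%, 77.6% and 88.4%, in that order. The 3 became 3640 and 5 (week 2 controls 0 and 1) and 751 and 0 (week 15 controls 0 and 1). The clock gene Per2 was 3.77 ± 0.54 higher at week 25 (adjusted p = 0.00534), as 5 of 18 clock genes were (camera adjusted p = 0.0147, adjusted p with an estimated correlation for this and the next lists from 0.466 to 0.481). Basal keratinocyte genes had 5 of 13 higher (6.15e-05), Krt15 by 1.07, and DNA methylation genes 5 of 20 (0.00249), Dnmt3a and Tet3 by 1.15 each. Sebaceous genes had 8 of 23 lower (6.15e-05), Elovl3 by -2.40, and stress keratins 9 of 35 lower (0.000164). Abundant genes at large stood higher in week 2 control 1 than in week 2 control 0 (median log2 0.45 at 0.4 to 1 counts per base and 0.88 above 1). List sums of that library may in part reflect its depth. Week 2 control 1 stood apart in sebaceous genes, which summed to 6964 CPM there, 3698 in week 2 control 0 and 3391 and 3600 in week 25. Without it no sebaceous gene was called and Elovl3 stood at -0.86 (adjusted p = 0.155). None was called without week 25 control 0 or 1 either (Elovl3 -2.22 and -2.58, adjusted p = 0.128 and 0.111). Leaving out week 2 control 1, week 25 control 0 or week 25 control 1 left 0, 0 and 2 basal keratinocyte, 2, 2 and 0 DNA methylation, 3, 2 and 2 clock and 1, 0 and 1 stress keratin genes. Leaving out week 2 control 0 left 8, 10, 5 and 13 of these and 13 sebaceous genes. Other lists moved in this comparison too. Proliferation (4 of 30, 0.000164) and WNT genes (8 of 24, 1 lower, 0.0101) lay higher. Differentiation (0 of 29, 0.000394), hair follicle (1 of 29, 0.000548) and markers of fibroblasts (3 of 15, 0.00156), adipocytes (3 of 8, 0.0024), Langerhans cells (4 of 14, 0.00567) and neutrophils (1 of 6, 0.0147) lay lower. Without week 2 control 1, week 25 control 0 or week 25 control 1 no proliferation, differentiation, adipocyte or Langerhans gene was called, with 0, 1 and 0 WNT, 2, 1 and 0 hair follicle and 2, 1 and 0 fibroblast genes. Without week 2 control 0 these were 7, 8, 19, 3, 3, 3, 7 and 2 in the order listed, with 1 WNT gene lower and 1 differentiation gene higher. RNA quality genes were not called (3 of 9 higher, 1 lower, 0.122), and summed to 4799 CPM in week 2 control 1 against 2718 in control 0 and 2931 and 2775 in week 25. The difference rose with exon length across genes (Spearman 0.359), and 624 genes were called with the trend removed. Age and day of collection cannot be separated in this design. Over the 3 control groups 661 genes differed (2686 by DESeq2, 2375 with no filter, 113 with the length trend removed), which became 1 to 3924 when single libraries were left out. It was 3924 without week 2 control 0 and 1 without week 25 control 1, and for the others 122 (week 2 control 1), 1817 and 505 (week 15 controls 0 and 1) and 2 (week 25 control 0).

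Tumors were compared with whole skin of control mice. No gene was called by edgeR among 14661 (smallest adjusted p = 0.371), with 813 at an unadjusted p under 0.05, and DESeq2 called 66. The values with the smallest p were all lower in tumor. The keratin gene Krt77 (chromosome 15, 101859856 to 101869618) stood at 19.6 ± 1.18 CPM in tumor and 191 ± 38.9 in whole skin (-3.36 ± 0.26, adjusted p = 0.371). Wfdc18 stood at 1.38 ± 0.948 and 65.7 ± 45.2, the alcohol dehydrogenase gene Adh6a at 2.30 ± 0.941 and 39.7 ± 4.64. The claudin gene Cldn8 stood at 4.16 ± 0.486 and 32.2 ± 8.16, and Ces1d at 56.9 ± 2.91 and 144 ± 13.8 (adjusted p of these from 0.834 to 0.891). The whole skin libraries stood further apart than any other pair, and control 1 lay near the tumors in UVB-response genes. Il19 stood at 0 and 41.7 CPM in whole skin and at 75.8 and 80.1 CPM in tumor, and Oas3 at 5.90 and 25.9 CPM against 61.2 and 75.9. Without whole skin control 1 the 3 remaining libraries gave 5488 calls with 1 residual degree of freedom, without control 0 2986, and without tumor 0 or 1 they gave 5 and 6. All 16 libraries in 1 fit gave 7 calls, 15 of them without whole skin control 1 gave 969, chosen after the result was seen, and no filter gave 1.

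As lists, several groups lay higher in tumor by camera, with 0 members called in each and adjusted p from 0.587 to 0.624 with an estimated correlation for all lists called. Higher were interferon response (5.22e-27, median log2 1.23, Cxcl9 at 2.11 ± 0.56), stress keratins (2.17e-13, Serpinb3a at 1.97), matrix remodelling (2.17e-13) and inflammatory mediators (3.89e-13; Ptgs2 at 2.03). So were markers of neutrophils (6.6e-13, median 1.55), macrophages (1.63e-09), fibroblasts (3.79e-07) and endothelium (4.13e-06). Proliferation (0.000459), AP-1 (0.000448, with Junb the 1 member passing adjusted over the list alone), hypoxia (0.000405), differentiation (0.028), epithelial-mesenchymal transition (0.0342) and EGFR genes (0.0342) lay higher too. The rises of fibroblast, endothelial and hypoxia genes rest largely on control 0, since control 1 summed above tumor 0. Their sums in whole skin controls 0 and 1 were 1153 and 2202, 500 and 1006, and 2442 and 4017 CPM. In tumors 0 and 1 they were 2139 and 2804, 856 and 1065, and 3862 and 4075 CPM. In the other lists that lay higher both controls summed below both tumors. Mean log2 CPM of differentiation genes was yet 7.29 in control 1 and 7.27 in tumor 0. Lower by camera were dendritic epidermal T cell markers (4.52e-06, 3 of 7 passing adjusted over the list alone, Cd3g at -2.21 ± 0.48), adipocyte markers (4.36e-06; 1 passing adjusted over the list alone), the clock (0.00118), hair follicle (0.0055), sebaceous genes (0.00804) and T and NK cell markers (0.0388). The p53 targets (0.861, camera up, median -0.07, mean -0.05), WNT genes (0.849, camera up, median -0.02, mean -0.08) and muscle markers (0.688, camera up, median -0.08, mean -0.01) were not called, nor were the remaining lists (0.0592 to 0.907). Without whole skin control 1, 29 interferon genes, 28 stress keratins and 17 fibroblast markers were called up, against 22, 14 and 5 without control 0 and 0 without either tumor. Adipocyte markers summed to 776 and 1713 CPM in whole skin controls 0 and 1 and to 783 and 973 in tumor. Their median went from -1.01 to -0.03 without control 1 (1 up, 2 down), and 12 were called down without control 0. Without control 0 the medians of hair follicle genes and of T and NK cell markers turned from -0.65 to 0.44 and from -0.59 to 0.08.

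Tumors were also set against UVB epidermis of the same week, both exposed but different in tissue. Skeletal muscle genes led the rises. Neb, the nebulin gene (chromosome 2, 52136647 to 52338798), stood at 830 ± 67.5 CPM in tumor and 3.98 ± 0.886 in UVB epidermis (7.72 ± 0.44, adjusted p = 1.3e-06). Pygm, Myom1, Ryr1 and Flnc were higher by 7.75 ± 0.47, 8.33 ± 0.52, 6.77 ± 0.44 and 8.38 ± 0.55 and Pde4dip by 5.06 ± 0.31. Krt77 was lower (-4.49 ± 0.31, adjusted p = 2.27e-06; 19.6 ± 1.18 against 445 ± 17.2 CPM), as were the epidermal genes Skint9 (-2.61 ± 0.22), Sp6 (-2.17 ± 0.18), Tesc (-3.90 ± 0.32) and Cldn23 (-4.01 ± 0.33). In all 4469 of 15126 genes were called, 2543 higher and 1926 lower. All 20 muscle markers were higher (camera adjusted p = 2.77e-28, adjusted p = 0.0994 with an estimated correlation). So were 16 of 16 endothelial (2.55e-13), 16 of 18 fibroblast (7.48e-14) and 19 of 27 matrix genes (3.52e-10), each at adjusted p = 0.0994 with an estimated correlation. The same held for 14 of 16 macrophage (2.16e-07) and 10 of 11 mast cell markers (7.01e-09), at adjusted p = 0.153 with an estimated correlation, and 18 of 29 differentiation genes were lower (1.72e-10, adjusted p = 0.335 with an estimated correlation). Proliferation genes (0 of 30, 0.0719) and interferon genes (2 of 30 up, 0.655) were not called by camera. Whole skin against control epidermis, the matching tissue comparison without exposure, called 8409 of 15126 genes (4826 higher, 3583 lower), with the same 20 muscle markers higher (7.59e-16, adjusted p from 0.224 to 0.71 with an estimated correlation over its called lists). Of the 2543 genes higher in tumor than in UVB epidermis 2379 were also higher in whole skin than in control epidermis (811 if independent), and of the 1926 lower genes 1804 were also lower (456 if independent). Both comparisons came from the same fit, so the counts given for independence are a rough guide only. Only the 4 libraries compared gave 6974 calls for tumor against UVB epidermis. The tumor calls numbered 2089 without UVB epidermis 1, and 2658 and 2760 without tumors 1 and 0.

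**Figure D4:**
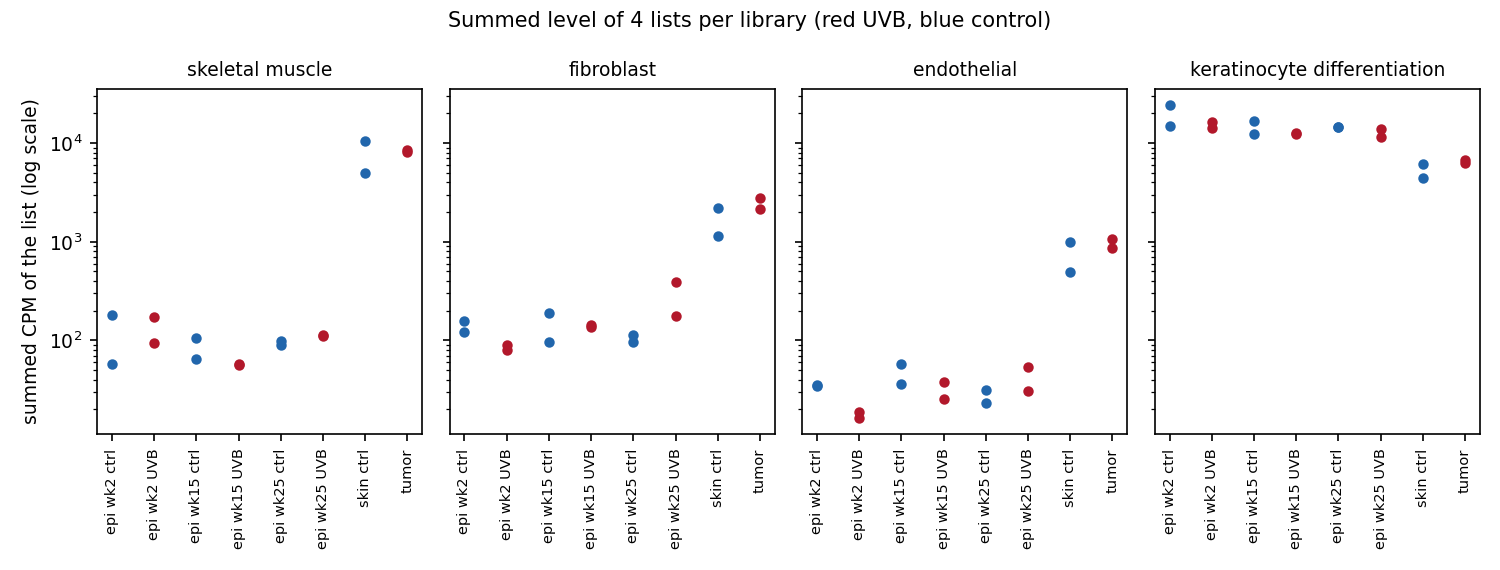
Points give the summed level of 4 lists in each of the 16 libraries in CPM on a log axis, by group, with UVB in red and control in blue. Summed muscle markers lay between 55.9 and 179.8 CPM in the 12 epidermis libraries and between 4936 and 10411 CPM in whole skin and tumor, and summed differentiation genes were lower in whole skin and tumor than in every epidermis library.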

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

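The tests of a difference between weeks were planned, and the tests of the shallow library, of the control change and of the part without a length trend were chosen after the result was seen. What brought up each result here is that the effect of UVB in epidermis differed between collection times by a test of the difference itself, over all 3 weeks (215 genes) or between weeks 25 and 2 (1067 genes). Among the genes with the smallest p over the 3 weeks, the UVB effect at weeks 2, 15 and 25 was 1.59, 0.21 and -1.67 for Ago2 (adjusted p = 0.00459) and 1.97, -0.29 and -1.72 for Zbed6, a transposon-derived transcription factor gene (adjusted p = 0.00832). At adjusted p = 0.0171 each stood the retinol dehydrogenase gene Dhrs9 (1.22, -0.08 and -1.27), Eda2r (4.46, 1.98 and -0.04), Tiparp (1.45, -0.08 and -0.48), the aminopeptidase gene Lnpep (0.42, -0.73 and -2.10), Nav3 (2.16, -0.51 and -2.30) and Ctsz (-3.03, -0.84 and 0.90).

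Of the lists, p53 targets (camera adjusted p = 0.000921; adjusted p = 0.25 with an estimated correlation) and EGFR ligands and receptors (0.00947; adjusted p = 0.281 with an estimated correlation) had a lower UVB effect at week 25 than at week 2, with 5 of 30 and 4 of 12 members called. Ereg and Epgn, which encode EGFR ligands, moved by -1.67 and -1.94. Mean log2 CPM of p53 targets rose in controls, from 5.666 and 5.510 to 5.929 and 5.947. In UVB it went from 6.060 and 6.317 to 5.988 and 6.002. For EGFR genes it rose in controls from 6.405 and 6.301 to 6.810 and 6.636. In UVB it fell from 6.457 and 6.561 to 6.265 and 6.388. Summed CPM of p53 targets was 2959 and 3334, then 3271 and 3250 in controls, and 3407 and 3640, then 2876 and 3045 in UVB. Part of both shifts may therefore lie in the controls. A higher effect at week 25 was found for matrix remodelling (8 of 20; 5.03e-08; adjusted p = 0.235 with an estimated correlation), fibroblast (9 of 15; 2.1e-10), adipocyte (2 of 8; 0.000811), Langerhans and dendritic cell (6 of 14; 7.41e-08) and macrophage markers (3 of 13; 0.000708), each of the last 4 also at adjusted p = 0.235 with an estimated correlation. It was also found for endothelial markers (2 of 9; 0.00687; adjusted p = 0.25 with an estimated correlation), inflammatory mediators (3 of 19; 0.0096), epithelial-mesenchymal transition (5 of 14; 0.00498) and neutrophil markers (2 of 6; 0.0298), the last 3 at adjusted p = 0.281 with an estimated correlation.

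Of the 1067 genes, 54.5% were still called without week 2 control 1, the shallowest library, which argues against that library as the only source. A lower UVB effect at week 25 than at week 2 went with change among the controls, since in 82.8% of those 618 genes the control groups differed between weeks by more than the UVB groups did, and the falls of Ago2 and Zbed6 may therefore lie in the controls. The same share was 37.9% among the 449 genes with a higher effect, which argues against change among the controls as the source of that direction as a whole, but not for the 170 genes behind that share, such as Ctsz (controls from 98.2 to 18.9 CPM, UVB from 12.3 to 35.1), or for adipocyte markers (sums of 322 and 422 CPM, then 153 and 144 in controls, and 165 and 139, then 203 and 188 in UVB). With each library's trend over exon length removed, 666 genes were called, and the 609 called either way had a median absolute log2 difference of 2.12 before and 2.09 after (median standard error 0.42 and 0.40). These 609 were picked as still called with the trend out, so their steady median does not by itself weigh against a length trend. It shows only that they also differed with the estimated trend removed. The 458 others kept their sign while their median fell from 1.13 to 0.79 (0.26 and 0.25), so calls ended because folds shrank, and there a length trend, from the samples or from library preparation, and a change in the response cannot be told apart.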

How the results depend on the processing

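Tests without the length trend, of counts corrected for the ceiling, of genes far from it, and without whole skin control 1 in a wider fit were chosen after the result was seen. Of 622 named genes called, 237 kept their call in every alternative. Of values not called, 5 changed sign: Adig at week 2 without control 1 (0.11, range -1.92 to 0.11), Tpsab1 at week 2 without control 0 (3.20, range -0.9998 to 3.20), S100a8 at week 15 with the length trend removed (-0.049), and Krt35 (0.46, range -2.88 to 0.46) and Lgr5 (0.24, range -1.92 to 0.24) in tumor without whole skin control 0, ranges being over libraries left out. All counts of calls at an adjusted p under 0.05 stayed within 1.5 times of the reported count with genes far from saturation only. Counts that moved further are given below, and the cause was not tested. Only the 4 libraries compared gave 684 at week 2, 4562 at week 25 and 6974 for tumor against UVB epidermis. All 16 libraries gave 234 at week 15, 1779 at week 25 and 7 for tumor against whole skin, and 15 libraries without whole skin control 1 gave 969. No filter gave 1146 at week 15, 1 in tumor, 794 and 1612 for the difference over 3 weeks and between weeks 25 and 2, and 2375 for controls. The length trend removed gave 92, 666 and 113 for the last 3 of these, and DESeq2 1123, 1758 and 2686, with 1006 at week 15 and 66 in tumor. For the UVB effect between weeks 15 and 2 and weeks 25 and 15, no filter gave 26 and 15 and DESeq2 50 and 63. For controls between weeks 25 and 2 and weeks 15 and 2, no filter gave 2808 and 1075, the length trend removed 624 and 1 and DESeq2 3030 and 1297. The count between weeks 15 and 2 was also 1 by median-of-ratios size factors, 1 on saturation-corrected counts and 0 with the stricter filter. Leaving out 1 library in turn, where a lone sample is assumed to vary like the other groups, gave 125 to 4377 at week 2, 26 to 1463 at week 15, 519 to 976 at week 25, 2816 to 4470 for the mean over weeks, 5 to 5488 in tumor against whole skin, 1 to 2280 and 71 to 3454 for the 2 differences between weeks, 1 to 3924 for controls, 2089 to 3405 for tumor against UVB epidermis and 6225 to 8923 for whole skin against epidermis. Counts for the 4 pairs of weeks without single libraries stand beside those results.

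Samples share only a number, and a block for it gave 235 calls for tumor against whole skin, 1744 for tumor against UVB epidermis and 5309 for whole skin against epidermis. It gave 1750 at week 2, 587 at week 15, 2277 at week 25 and 2976 for the mean, and of 71 list calls it ended that of EGFR genes in tumor (0.0835) and changed no other. Deviations of same-numbered samples correlated at -0.0838, -0.0334 and 0.241 at weeks 2, 15 and 25 and at -0.0312 between whole skin and tumor. Removing the length trend kept 66 of the 71 list calls, fry 32 and an estimated correlation 0. No formal test of a sample against the fit was run, and depths of 2905165 to 7959503 counts limit what can be said of genes with few counts.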

Other observations

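The test of deeper tissue and the split tests were planned before their results were seen, and the tests of whole skin control 1 were chosen after the result was seen. Genes named in this and the next paragraph, other than Wfdc18 and Spink7, were chosen after their values were seen. The casein genes Csn1s1 (chromosome 5, 87666208 to 87682577), Csn2 and Csn3 stood at 14.0, 9.15 and 8.65 CPM in whole skin control 0 and at 91.3, 55.6 and 59.6 CPM in control 1, and at 0 CPM in both tumors, though edgeR called no gene there (813 at an unadjusted p under 0.05, 66 called by DESeq2). Wfdc18, expressed in mammary tissue, stood at 33.8 and 97.7 CPM in whole skin and at 0.71 and 2.05 CPM in tumor.

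Among genes called at all 3 weeks were several outside the lists. As the mean over weeks (n = 6 each), Spink7 rose by 4.06 ± 0.30 (adjusted p = 1.41e-05), the steroid reductase gene Akr1d1 by 4.05 ± 0.40 (adjusted p = 7.91e-05), Ms4a6d by 3.83 ± 0.38 (adjusted p = 8.89e-05), the DNA sensor gene Ifi202b by 3.47 ± 0.29 and the connexin gene Gjb1 by 3.20 ± 0.34. Lrrc15, Tgm6 and Gprc5d moved by -4.22, -4.16 and -3.97.

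The 2 whole skin controls differed in UVB-response genes and in tissue markers, with muscle markers summing to 4936 and 10411 CPM in controls 0 and 1, fibroblast 1153 and 2202, adipocyte 776 and 1713, endothelial 500 and 1006, and T and NK cell markers 271 and 122. Abundant genes at large stood higher in control 1, by a median log2 of 0.55 at 0.4 to 1 counts per base and 0.77 above 1. Part of the higher sums may therefore reflect depth and the ceiling, which was not tested for these markers. Of 122 genes raised by UVB at all 3 weeks in epidermis, 104 were higher in whole skin control 1 than in control 0 with a median log2 difference of 1.06 (-0.10 to 0.23 in the central 95% of matched random lists), against 1.28 and 1.17 in the tumors, and 106 of the 117 lowered genes, those past the filter in skin and tumor libraries, had a median of -0.59. Over the 57 of the 122 under 0.1 counts per base of exon the median was 0.805, above the depth ratio of 0.713 between the libraries, which argues against depth and saturation, and the tumor medians, of which the lower was 1.17, argue against a swap with a tumor if control 0 is typical. The ratio of its median to the mean tumor median was 0.864, so UVB-exposed or inflamed skin in the library is a candidate explanation. Each of these medians is taken against control 0, so an unusual control 0 would give them too, and that and the difference in tissue stay open.

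Tumor libraries held deeper tissue, and so did whole skin. Of the genes called higher in tumor than in UVB epidermis, 93.6% were also higher in whole skin than in control epidermis, so muscle, stroma and vessel genes in that comparison may reflect the tissue taken rather than the tumor, and how much of the tumor stroma is left beyond that stays open.

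The calls for the mean over weeks were set against regrouped libraries. Of 100 splits of 2 and 2 within each week, the real one included, 1 called as many genes (3973, the real one), and the highest other called 6. Of 100 splits of any 6 against 6, 1 called as many, and the highest other called 2342, in a split that kept 10 of the 12 libraries as in the real one.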
